A study of Homo sapiens with 3 samples.

How the data were processed

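Chromatin immunoprecipitation followed by sequencing (ChIP-seq), which maps where a protein sits on the genome, had been performed in DU145, an established prostate adenocarcinoma cell line derived from a brain metastasis. There were 3 libraries, each alone in its group. ZMYND11 (also called BS69) was precipitated from parental cells and from cells in which ETS1 had been knocked out, and ETS2 was precipitated from ETS1-knockout cells. Groups were taken from the sample titles. No replicate and no input or control library was analysed here, so no difference between conditions could be set against a spread between replicates.

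The authors deposited 1 list of regions per library. Each line holds a chromosome, a start and an end, and no header, score, fold, p-value or read count. Per the submitters' processing notes, Bowtie2 version 2.0.6 and the genome build hg19 were used. The peak caller, its threshold, any control used in calling and the depth of the libraries are not given in the sources used here. Precision per region and detection limits therefore could not be derived, and a difference in the number of listed regions can come from depth, from the efficiency of the precipitation or from the calling threshold as well as from binding. No region was longer than 501 bp in any of the lists. No list contained a duplicate or overlapping regions. Coordinates are printed as deposited, and whether starts are counted from 0 or 1 is not stated.

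None of the lists was in genomic order. What the order stands for is not stated. It was used as the place of a region in its list, after agreement of the places between lists had been examined. Some of the analyses fixed in advance needed a score, a genome sequence or an annotation of hg19. The alternatives that would have ranked regions by score were replaced by alternatives on list place, which were chosen after the data were examined. The planned analyses of gene starts and gene features, of ETS and AP-1 motifs, of placement matched on gene starts and of the 13 fixed gene lists were not run, and no gene was assigned to a region. The table of genes at hand was on another build and was not used here. For the same reason the loci of ETS1, ETS2 and ZMYND11 themselves were not analysed here, and the knockout was not checked from these data.

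Regions of different lists were called shared where they overlapped by at least 1 bp. The number of shared regions was compared with 1000 random placements of the shorter list, keeping each region's width and chromosome, with a one-sided permutation p-value whose smallest possible value is 0.001. Placement had been planned in assembled sequence only. Without the genome it covered the span between the outermost regions of the 3 lists on each chromosome, gaps included, which can lower the random overlap. An added alternative shifted each region by up to 100 kb at random and so kept the local density of regions. Other alternatives required a reciprocal overlap of 50% of both regions, accepted midpoints within 1000 bp, left out mitochondrial regions and regions wider than 3 times the median, took the first 50% of each list, or took the longer list to the length of the shorter. Shares of regions have 95% Wilson intervals and were compared with two-sided Fisher's exact tests. Spearman correlations of list places used 100000 permutations. Chromosome shares were tested with Fisher's exact test and Benjamini-Hochberg adjustment over 24 chromosomes. Neighbouring regions are not independent, and all of these tests compare lists from single libraries, not conditions.

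Most regions named in the text followed a rule fixed before the data were examined, with list place standing in for the score. They are the first 10 regions of each list, the regions in all 3 lists, and the first 10 regions shared by ZMYND11 in both cell types and by both factors in knockout cells. The rule allowed up to 10 regions in all 3 lists, but all 11 found are named. Regions far from any region of another list were added after their positions were seen. The densest megabases were not part of the rule either. The overlap procedure was tested on simulated data: of 200 planted overlaps, 200 were recovered in every run for each of the 3 pairs. Of 20 runs with unrelated lists, 1 passed the 0.05 threshold for parental against knockout ZMYND11, 0 for ETS2 against knockout ZMYND11 and 2 for parental ZMYND11 against ETS2. The unrelated lists were drawn by the same rule as the random placements, and planted regions were laid onto regions of the other list. Both outcomes were thus largely fixed in advance. The runs check the procedure, and do not test how clustering of regions affects the p-values. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.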

Results

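The regions bound by ZMYND11 and ETS2 were compared in DU145 prostate cancer cells with and without ETS1. ETS1 and ETS2 are related transcription factors that respond to Ras signalling, and ZMYND11 is a chromatin reader and co-repressor. The title of the study places ZMYND11 as a partner through which the ETS factors act in opposite ways. The ZMYND11 list of parental cells held 536 regions covering 0.260 Mb. The ZMYND11 list of ETS1-knockout cells held 15676 regions covering 7.72 Mb, and the ETS2 list of ETS1-knockout cells held 1020 regions covering 0.504 Mb. Median widths were 493, 496 and 497 bp in the same order. Each list came from 1 library, so none of the values below has a replicate error. Coordinates are on hg19, and gene features were not analysed here.

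The comparison of ZMYND11 between parental and ETS1-knockout cells asks where the co-repressor was found when ETS1 was absent. The knockout list held 29.2 times as many regions as the parental list. Only 56 of the 536 parental regions overlapped a knockout region, a share of 10.4% (95% Wilson interval 8.13 to 13.3%), and 480 did not. The 10 regions listed first in knockout cells were all absent from the parental list. Of the whole knockout list only 0.357% of regions overlapped a parental region, so few would be found among any 10. They lay on chromosome 11 (62608870 to 62609370 and 65658840 to 65659341), chromosome 1 (149223753 to 149224254 and 148241470 to 148241970), chromosome 17 (57920396 to 57920897, 79825926 to 79826427 and 8076504 to 8077002), chromosome 14 (31091150 to 31091650), chromosome 9 (130208169 to 130208668) and chromosome 19 (10224340 to 10224841). Of the 10 regions listed first in parental cells, 3 overlapped a knockout region. These were chromosome 2, 33141256 to 33141726, at place 1 of the parental and place 111 of the knockout list, chromosome 8, 145011631 to 145012124, at places 5 and 752, and chromosome 4, 49313582 to 49314040, at places 10 and 14439. The other 7 were on chromosome 7 (5567950 to 5568449), chromosome 17 (79478772 to 79479271), chromosome 12 (6646759 to 6647249), chromosome 1 (16466807 to 16467302), chromosome 4 (49515295 to 49515795), chromosome 8 (146016869 to 146017364) and chromosome 14 (69256518 to 69257011).

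The 56 shared ZMYND11 regions were more than random placement gave. A mean of 3.75 ± 1.99 (SD, 1000 placements) regions overlapped by chance, so the observed number was 14.9-fold higher (one-sided permutation p = 0.001, the smallest the placements can give). Against shifts of up to 100 kb, which keep the local density of regions, the excess was 4.54-fold (mean 12.3 ± 3.45, permutation p = 0.001). The shared regions were spread unevenly along the knockout list and leaned to its early part, with a median place of 4440 of 15676. Of the 56, 15 fell in its first 10%, 9 in the next 10% and 10 in the last 10%. Further shared regions that stood early in the parental list were on chromosome 17 (19091275 to 19091552, places 13 and 30), chromosome X (153586254 to 153586719, places 17 and 9765), chromosome 1 (156264776 to 156265243, places 26 and 9688), chromosome 1 (15743322 to 15743791, places 52 and 4800), chromosome 16 (87865347 to 87865829, places 55 and 2397), chromosome 9 (135905976 to 135906473, places 58 and 3625) and chromosome 20 (60881707 to 60882202, places 64 and 150). Among the 56 regions the places in the 2 lists were correlated across regions (Spearman's rho = 0.41, permutation p = 0.002, Benjamini-Hochberg adjusted p = 0.003 over 3 pairs of lists).

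Midpoints within 1 kb of a knockout midpoint were found for 73 parental ZMYND11 regions (13.6%, interval 11.0 to 16.8%), overlapping regions included, against a mean of 24.6 ± 4.71 after shifts. Without the overlapping regions 17 were left, against 12.4 ± 3.38 (one-sided permutation p = 0.118), so an excess within 1 kb beyond the overlaps was not detectable. The shifts moved all 536 parental regions, and more of them were without overlap after shifts than the 480 observed. The comparison is therefore of numbers and not of shares, and leans towards finding no excess. At 1 to 10 kb there were 127 parental regions against 107 ± 8.08 (1.18-fold, one-sided permutation p = 0.006), and at 10 to 100 kb there were 161 against 223 ± 9.06. Each region counts in 1 distance band only, so an excess at short distances lowers the numbers farther out. A further 175 parental regions (32.6%) had no knockout region within 100 kb, against 181 ± 4.94 after shifts. The earliest of these in the list were on chromosome 21 (32906776 to 32907258 and 37576651 to 37577141), chromosome 8 (125132398 to 125132883) and chromosome 2 (15732820 to 15733318), which were picked after their positions were seen.

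**Figure D1:**
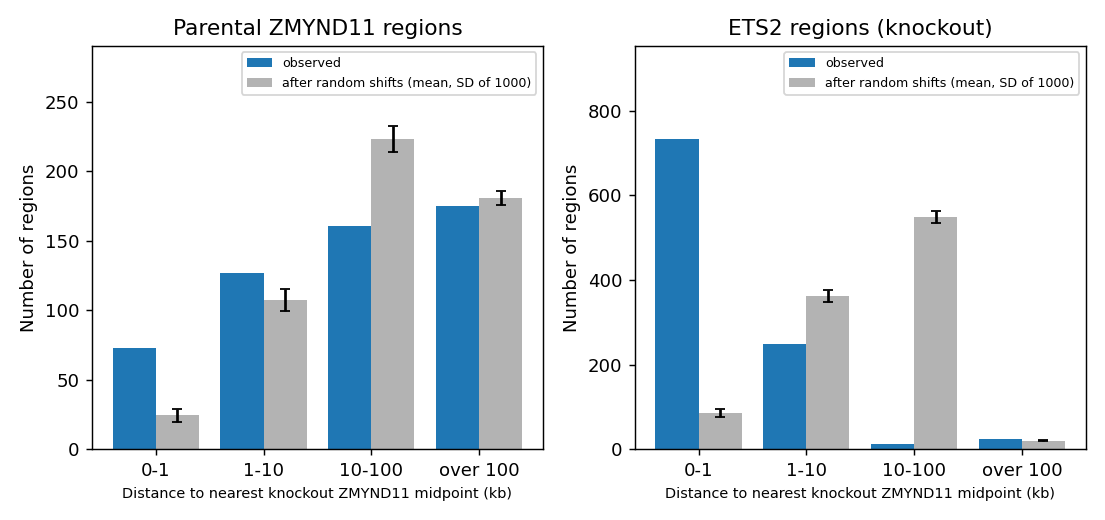
Number of regions (vertical axis) by distance in kb from their midpoint to the nearest knockout ZMYND11 midpoint (horizontal axis), for parental ZMYND11 (left) and ETS2 (right), with blue bars for observed regions and grey bars for the mean and SD of 1000 random shifts of up to 100 kb. Within 1 kb there were 73 parental ZMYND11 regions and 733 ETS2 regions, both above their shifted means of 24.6 and 86.0, with overlapping regions included.

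The comparison of ETS2 with ZMYND11 in the same ETS1-knockout background asks whether both proteins occupied the same places. Of 1020 ETS2 regions, 582 overlapped a knockout ZMYND11 region by at least 1 bp (57.1%, interval 54.0 to 60.1%). The share depended on the rule: 733 ETS2 regions (71.9%) had a ZMYND11 midpoint within 1 kb, 424 (41.6%) overlapped reciprocally by 50%, and 385 (37.7%) overlapped one of the first 1020 ZMYND11 regions. Midpoints of overlapping regions were a median of 138 bp apart (quartiles 56.5 and 258 bp). Random placement gave 8.63 ± 2.87 overlaps, so the observed number was 67.4-fold higher (one-sided permutation p = 0.001). Against shifts of up to 100 kb it was 13.4-fold higher (mean 43.3 ± 6.46, permutation p = 0.001). Both p-values are the smallest that 1000 placements can give.

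The regions listed first for ETS2 were largely those listed first for ZMYND11. Of the first 10 ETS2 regions, 9 overlapped a knockout ZMYND11 region. Chromosome 11, 62608869 to 62609368, was at place 2 for ETS2 and place 1 for ZMYND11. Chromosome 17, 57920783 to 57921284, was at place 3 in both lists, and chromosome 1, 149223791 to 149224292, was at places 4 and 2. Chromosome 11, 65658735 to 65659234, was at places 5 and 7, and chromosome 11, 65274531 to 65275031, at places 6 and 13. Chromosome 9, 130207990 to 130208491, was at places 8 and 6, chromosome 17, 79825671 to 79826166, at places 10 and 8, and chromosome 1, 148241409 to 148241910, at places 11 and 4. Chromosome 17, 18966821 to 18967314, was at places 7 and 35. The region at place 1 for ETS2, chromosome 2, 33141255 to 33141740, was at place 111 for ZMYND11. Over the 582 shared regions the places were correlated (Spearman's rho = 0.63 across regions, permutation p = 1e-05, the smallest the permutations can give, adjusted p = 3e-05).

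The share of ETS2 regions with ZMYND11 went from 82.4% (interval 73.8 to 88.5%) in the first 10% of the ETS2 list to 37.3% (28.5 to 46.9%) in the last 10%. Seen from ZMYND11, 464 of the 582 shared regions were in the first 10% of its list. In that part 29.6% of the ZMYND11 regions overlapped an ETS2 region, in the next 10% of the list 4.53%, and in the last 10% 0 of 1567.

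**Figure D2:**
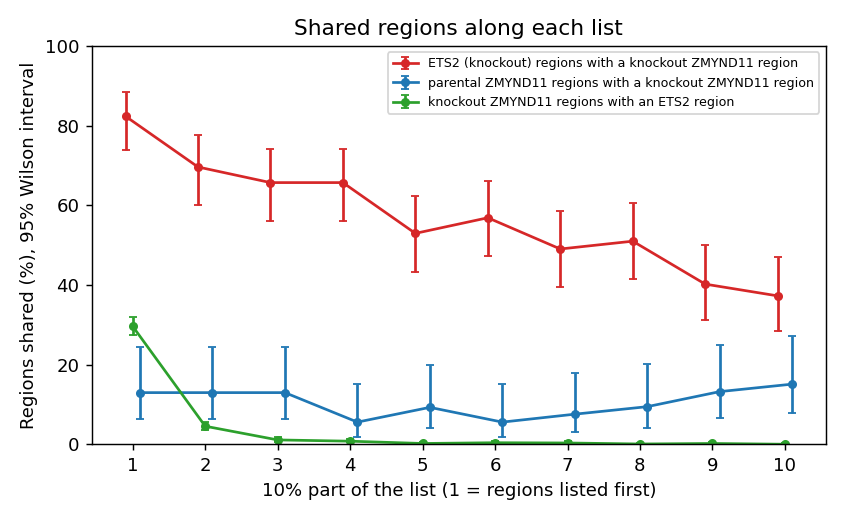
Percentage of regions shared with another list (vertical axis, with 95% Wilson intervals) in each 10% part of a list in the order deposited (horizontal axis, part 1 holding the regions listed first), for ETS2 and parental ZMYND11 regions with a knockout ZMYND11 region and for knockout ZMYND11 regions with an ETS2 region. The ETS2 values go from 82.4% to 37.3%, while the parental ZMYND11 list has 10.4% shared over its whole length.

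**Figure D3:**
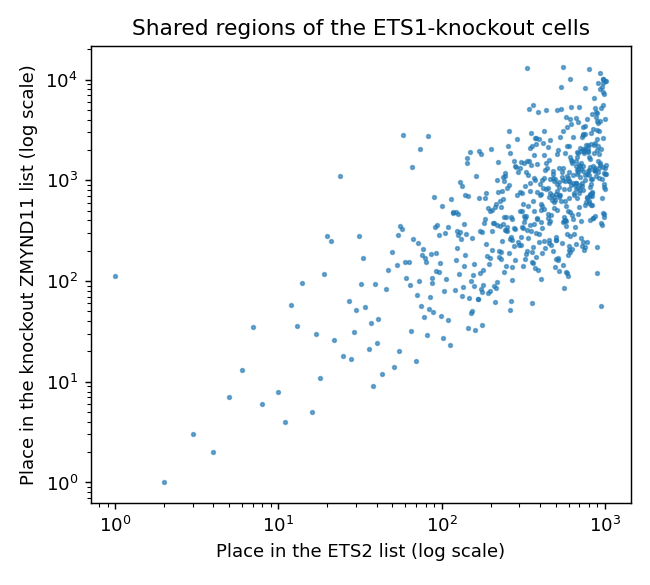
Place in the ETS2 list (horizontal axis, log scale) against place in the ZMYND11 list (vertical axis, log scale) of the 582 regions that overlapped in ETS1-knockout cells, 1 point per region. Spearman's rho is 0.63.

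ETS2 regions without ZMYND11 overlap numbered 438. Of these, 151 had a ZMYND11 midpoint within 1 kb. When all 1020 ETS2 regions were shifted by up to 100 kb, 43.1 ± 6.48 lay that near without overlap (observed 3.5-fold higher, one-sided permutation p = 0.001). More regions were without overlap after shifts than the 438 observed, so the 3.5-fold compares numbers and not shares. The nearest midpoint was at 1 to 10 kb for 249 ETS2 regions, below the 363 ± 14.1 after shifts, and at 10 to 100 kb for 14, below 549 ± 13.9. For the remaining 24 it was farther away, or the ZMYND11 list had none on that chromosome. Each region counts in 1 distance band only, so the 733 ETS2 regions within 1 kb left fewer for the bands farther out. The lower numbers at 1 to 100 kb therefore do not show that ETS2 regions avoided these distances. The first 2 of the 24 in list order were both on the mitochondrial sequence (3 to 504 at place 9 and 16128 to 16629 at place 23), at its opposite ends as numbered. The mitochondrial genome is circular, so these ends adjoin. The next were chromosome 7, 56534455 to 56534950, 63538858 to 63539359 and 57187774 to 57188274, and chromosome 3, 75786759 to 75787249. In the other direction, the ZMYND11 regions listed first with no ETS2 midpoint within 100 kb were chromosome 9, 139617026 to 139617524 (place 43), chromosome 5, 1458010 to 1458511 (place 65), and chromosome 1, 8919008 to 8919509 (place 110). These far regions were picked after their positions were seen.

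Parental ZMYND11 and knockout ETS2 shared 18 regions, which is 3.36% of the parental list (interval 2.14 to 5.25%) and 1.76% of the ETS2 list. Random placement gave 0.262 ± 0.527 (68.7-fold higher observed, one-sided permutation p = 0.001), and shifts of up to 100 kb gave 1.21 ± 1.11 (14.9-fold, permutation p = 0.001). The 18 regions showed no detectable agreement of list places (Spearman's rho = 0.21, permutation p = 0.398, adjusted p = 0.398), whereas the 14 that overlapped reciprocally by 50% gave rho = 0.56 (permutation p = 0.0402, not adjusted). Of the 18, 11 parental regions also overlapped a knockout ZMYND11 region, which among ETS2 regions is not a separate association, since 57.1% of all ETS2 regions did so. Counted from the parental list, 11 of the 56 regions with a knockout ZMYND11 region (19.6%) and 7 of the 480 without (1.46%) overlapped an ETS2 region (odds ratio 16.5, Fisher's exact test, two-sided, p = 1.13e-07). Counted from ETS2, 11 of the 582 regions with a knockout ZMYND11 region (1.89%) and 7 of the 438 without (1.60%) overlapped a parental region (odds ratio 1.19, Fisher's exact test, two-sided, p = 0.813).

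Counted from the ETS2 list, 11 regions overlapped a region of both other lists. In the order of the ETS2 list they were chromosome 2, 33141255 to 33141740, chromosome 1, 156736950 to 156737449, chromosome 17, 19091279 to 19091569, chromosome 20, 62587796 to 62588292, chromosome 22, 20861582 to 20862079, chromosome 14, 103985603 to 103986103, chromosome 6, 33244712 to 33245210, chromosome 1, 16840332 to 16840809, chromosome 19, 5680273 to 5680771, and chromosome 5, 180670810 to 180671306 and 176944144 to 176944630. Of the 11, 10 also met both lists when counted from the parental region. The chromosome 2 region was at place 1 of both the parental ZMYND11 and the ETS2 list.

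Over the whole lists, 582 of 15676 knockout ZMYND11 regions (3.71%, interval 3.43 to 4.02%) and 18 of 536 parental regions (3.36%, interval 2.14 to 5.25%) overlapped an ETS2 region (difference 0.354 percentage points, Fisher's exact test, two-sided, p = 0.815). With 1020 ETS2 regions against 15676 knockout regions, the knockout share was bound to be low, so this p-value says little about a difference. Over the first 50% of each list the shares were 4.36% and 4.10% (Fisher's exact test, p = 1). The first 536 knockout regions, as many as the parental list holds, overlapped an ETS2 region in 279 cases (52.1%, interval 47.8 to 56.3%). That value sets the beginning of one list against the whole of another, in an order whose meaning is not stated, and the difference of 48.7 percentage points therefore does not compare the 2 cell types on equal terms. The ETS2 list came from knockout cells alone, so ETS2 positions in parental cells did not enter the comparison.

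The lists also differed in how their regions fell on the chromosomes. Chromosome 5 held 76 ETS2 regions (7.45%, interval 5.99 to 9.23%) against 4.40% of the knockout ZMYND11 regions (odds ratio 1.75, Fisher's exact test, Benjamini-Hochberg adjusted p = 4.86e-04). Chromosomes 11 (8.53% against 5.75%, adjusted p = 0.003), 12 (7.65% against 5.39%, adjusted p = 0.0143) and 19 (11.0% against 8.67%, adjusted p = 0.0339) also held a larger share of the ETS2 list by the same exact test. Chromosomes 3, 7, 9, 10, 14 and 15 held a smaller one, with chromosome 15 at 1.08% against 3.14% (Fisher's exact test, adjusted p = 4.86e-04). Against the first 1020 ZMYND11 regions, only chromosome 5 passed (odds ratio 2.49, Fisher's exact test, adjusted p = 4.00e-04). Between the parental and knockout ZMYND11 lists, 0 of 24 chromosomes passed by Fisher's exact test with Benjamini-Hochberg adjustment, and 2 had an unadjusted p under 0.05.

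Among the densest megabases of each list, some were dense in several lists and others were not, which was not tested. On chromosome 19 from 1 to 2 Mb there were 74 knockout ZMYND11, 9 ETS2 and 6 parental ZMYND11 regions, the highest number for both ZMYND11 lists. On chromosome 11 from 65 to 66 Mb there were 17 ETS2 regions, the highest number in that list, with 70 knockout ZMYND11 regions and 1 parental region. Chromosome 14 from 105 to 106 Mb held 72 knockout ZMYND11 regions but 1 ETS2 and 0 parental regions, and chromosome 17 from 73 to 74 Mb held 69, 3 and 0.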

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

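The 3 pairwise overlaps stayed above random placement with permutation p = 0.001 under each of the 6 alternatives run for each pair. Of these, the first 50% of each list, the longer list at the length of the shorter and the shift of up to 100 kb were chosen after seeing the data. Across the alternatives the excess ranged from 4.54-fold (shift of up to 100 kb) to 62.5-fold (equal length) for ZMYND11 in parental against knockout cells. It ranged from 13.4-fold to 571-fold for knockout ZMYND11 against ETS2, and from 14.9-fold to 193-fold (first 50%) for parental ZMYND11 against ETS2. The highest folds came from small random means (0.144, 0.674 and 0.057), with 9, 385 and 11 shared regions against 56, 582 and 18 over whole lists. The size of the excess varied with the background (the shift), with how much of each list was used and with the overlap rule. For parental ZMYND11 against ETS2 it was 68.7-fold in the main analysis, 117-fold for reciprocal overlap and 37.8-fold for midpoints. Its direction did not change under these alternatives. The difference in ETS2 share between the knockout and parental ZMYND11 lists was the main result whose call changed: it was 0.354 percentage points over whole lists and 48.7 percentage points with the longer list at the length of the shorter, since the ETS2 overlap lies early in the knockout list and only the beginning of that list was then used. Its other 4 alternatives stayed without a detectable difference, although leaving out mitochondrial or wide regions could not change this result. The correlation of list places between parental ZMYND11 and ETS2 was 0.21 over 18 regions and 0.56 (permutation p = 0.0402) over the 14 with reciprocal overlap. Leaving out mitochondrial or wide regions removed 2 ETS2 regions, none of the shared ones and no ZMYND11 region. The 2 removed regions were mitochondrial, and neither ZMYND11 list held a mitochondrial region. For all 3 pairs this alternative therefore repeated the main analysis with new random placements and was no separate check. Settings fixed before the data were examined that ranked by score, used gene-start placement, or concerned gene starts, motifs and gene lists were not run. No replicate could be left out, with 1 library per group. No paired analysis was possible because each group had 1 library. Depth is unknown for these lists, so a region missing from a list was not listed at the authors' threshold, which does not show that it was unbound.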

Other observations

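All of the tests in this part were chosen after the result they bear on had been seen. No biological explanation other than the loss of ETS1 is named by the design, and with 1 library per condition it stays untested.

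The ZMYND11 list of parental cells was far shorter than that of knockout cells, 536 against 15676 regions. A shallower sampling of the same sites would leave a short list made mostly of knockout sites. Of the parental regions 10.4% were knockout regions (Wilson interval 8.13 to 13.3%, against a mark of 50% set after the overlap was known). By this share, shallower sampling alone is argued against, but not shallower sampling together with many background calls. Of the first 100 knockout regions 4 were in the parental list, against 0.357% of the whole knockout list. What the list order stands for is not stated, so the 4 of 100 does not bear on the question. The ETS2 list, of 1020 regions, shared 57.1% with the same knockout list. It came from the same knockout cells, however, so it is no measure of what a short list from parental cells would share. It stays open whether the parental library gave mostly background regions. Its overlap with the knockout list was 4.54-fold above local shifts, but this accounts for a small part of its regions. With the list of another factor, ETS2, its overlap was 14.9-fold above local shifts. Background that recurs between libraries would also exceed shifts, so these values cannot decide the question. Without an input library a weak precipitation and a change of binding cannot be told apart.

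ETS2 and ZMYND11 in knockout cells shared 582 regions, in a similar order. Artefact regions that appear in every library of this cell line would recur in the parental list. Of the 582, 11 did (1.89%, interval 1.06 to 3.35%), but the parental list met only 18 ETS2 regions in all and may itself be weak, so this does not exclude such regions. The chromosome 2 region listed first in both the parental ZMYND11 and the ETS2 list remains a candidate source of such signal, as do the other regions found in all 3 lists. Shared handling of the knockout cells, or open chromatin recovered by any antibody, cannot be told apart from joint binding of the 2 proteins. The overlap was 57.1%; how much any of these would give was not estimated, and no control precipitation from knockout cells was analysed here.

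Chromosome 5 held more ETS2 regions than the ZMYND11 list of the same cells would give. ZMYND11 sites standing higher in their list on this chromosome are argued against: with place in the ZMYND11 list held fixed in 50 strata, 37 of its ZMYND11 regions overlapped ETS2 against a mean of 22.6 ± 3.90 (SD, 10000 permutations), 1.63 times as many (two-sided permutation test, adjusted p = 0.010 over 24 chromosomes). Chromosome 14 had fewer, 14 against 28.9 ± 4.25 (permutation test, adjusted p = 0.005). This test covers only sites where both factors overlapped, while chromosome 5 held 76 ETS2 regions in all. Chromosome 5 held 3.14% of the first 1020 ZMYND11 regions against 4.40% of the whole ZMYND11 list, so its ZMYND11 sites did not gather early in that list. Segments within chromosome 5 that differ between the libraries, for example in DNA copy number between cultures, stay open: with list place and the chromosome mean removed, ETS2 overlap showed no detectable correlation between its ZMYND11 regions 1 to 10 Mb apart (one-sided permutation p = 0.273), and 37 overlaps are few for such a test. In consecutive 20 Mb windows from 0 to 200 Mb there were 4, 2.90, 7.27, 14.3, 13.9, 4.76, 13.0, 13.3, 16.3 and 21.1 ETS2 regions per 100 ZMYND11 regions. In the same order these values rest on 4, 2, 4, 9, 5, 1, 14, 12, 21 and 4 ETS2 regions. The whole lists held 1020 ETS2 and 15676 ZMYND11 regions, which is 15.4 ZMYND11 regions per ETS2 region. That ratio is the inverse of the window values and cannot be set beside them directly. The windows up to 40 Mb had the lowest values, and each window from 120 Mb on had 13.0 or more. This contrast between larger parts of the chromosome was not tested. A difference of the whole chromosome was not tested apart from binding.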
